A study of Homo sapiens with 21 samples.

How the data were processed

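The series holds RNA-seq libraries of K562, an established human line of chronic myeloid leukaemia cells in blast crisis with erythroid and megakaryocytic features, grown per the labels' protocols in RPMI 1640 with 10% fetal bovine serum. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from 1 µg of total RNA with a TruSeq RNA kit. The labels place 21 libraries in 7 groups of 3. Enhancer RNAs (eRNAs) are transcripts made from active enhancers, and per the series' design text an enhancer 34 kb upstream of MYB makes a pair of them, which were overexpressed separately. The labels call these experiments 34kn and 34kp, and each has its own control libraries. The third experiment holds an empty-vector group, a group labelled MYB overexpression and a group labelled NMYB overexpression. The design text speaks of full-length MYB and of an isoform truncated at the N terminus, and the label NMYB itself is not spelled out in the sources used here.

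The deposited values were raw counts of both kinds. For the eRNA experiments the authors deposited 1 file per library of exon bin counts, that is, of reads over the non-overlapping parts into which a gene's exons are divided by its transcripts. For the MYB experiment the authors deposited a single table of gene counts for 9 libraries. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.93 and aligned to GRCh38 with STAR 2.7.10a for the bins, or with HISAT2 2.2.1 for the gene table, which was counted with featureCounts 2.0.1. The annotation release, the strand setting of the counting and the treatment of reads with several alignments were not given in the sources used here. The bin files list 685251 bins, of which 225600 were 0 in all 12 libraries, under 57300 gene names. Of these names, 2582 join overlapping genes and hold 121224 bins. Of the 54718 names of single genes, 54583 were paired with a symbol, and the gene table lists 61541 genes, of which 61369 carry a symbol. All columns of values belonged to a labelled library. Lines of the bin files that name no bin were left out of library sizes and tests. Among all counted items of a library, reads outside annotated bins made up 29.5% to 32.8%, reads of low alignment quality 4.46% to 10.5% and ambiguous reads 0.0155% to 0.0225%.

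A read that spans several bins can be counted in each, so a sum over the bins of a gene is a sum of bin counts and not of reads. Bin counts and gene counts also differ in aligner and counting, so no model was fitted across the eRNA files and the gene table, and only fold changes were compared between them. Genes that overlap or share near-identical copies cannot be told apart where reads fit more than 1 of them. Without a stated strand setting, an antisense transcript such as MYB-AS1, which lies within MYB on the other strand, cannot be separated from its partner. Neither eRNA is annotated as a gene in GENCODE 29, which places 0 genes between HBS1L and MYB, so the level of the overexpressed eRNAs was not analysed here.

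Bin counts summed to between 36563252 and 41243796 per library and gene counts to between 16552237 and 24462819. The 10 highest genes held 2.21% to 4.02% of the bin counts and 6.79% to 8.24% of the gene counts. Replicates within a group differed by more than sampling noise in all 21 pairs, with a chi-square per degree of freedom of 1.59 to 51.7, so every library was kept as a replicate. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

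Comparisons, tests, the gene lists and the rule for named genes were chosen before the data were examined. Gene-level changes were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with a minimum count of 10 and a robust quasi-likelihood F test, two-sided, with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The 9 libraries of the MYB experiment were fitted together. Each eRNA experiment was fitted on its own 6 libraries, with bin counts summed per gene. The difference between the eRNA experiments was tested as an interaction over all 12 libraries. Exon usage was tested on the bins with edgeR's diffSpliceDGE, which compares each bin's log2 fold change with that of its gene, in genes with at least 2 bins past the filter, and gene-level p-values were combined with Simes' method. The design text names DEXSeq, which was not used here. A DEXSeq-type model in DESeq2 1.42.0, with a term per library, a term per bin and a bin by condition term, was an alternative. MYB bins were adjusted over all tested bins and, separately, over the MYB bins alone. Fold changes are log2 values with the standard error (SE) of the model. Levels are CPM scaled by TMM, given as mean ± SD with n = 3.

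The 29 gene lists cover MYB locus genes, the MYB family, reported MYB target genes, erythroid genes, fetal globin regulators, megakaryocytic genes, granulocytic and monocytic genes, stem and progenitor genes, DNA replication, mitosis, cyclins and CDK inhibitors, STAT5 and cytokine signalling, the BCL2 family, interferon response, NF-kB and inflammation, immediate early genes, amino acid stress and unfolded protein response, heat shock, cholesterol synthesis, glycolysis and hypoxia, splicing factors, chromatin looping and transcription cofactors, erythroid transcription factors, replication-dependent histones, mitochondrially encoded genes, small ribosomal proteins, and lymphoid, epithelial and fibroblast markers. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry (limma 3.58.1). Members changed were counted over all genes tested and adjusted over the list alone.

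Named genes are MYB, the 8 genes that rose and the 8 that fell with the largest absolute log2 fold change among genes past the threshold with at least 5 CPM in the higher group, no overlap between the libraries of the groups and an ordinary gene symbol, up to 3 changed members of each list by the smallest adjusted p, and every tested member of the MYB locus list. Named bins are every tested MYB bin and the 8 bins per direction, 1 per gene, with the largest change in usage, at least 50 counts in the higher group and no overlap in the bin's share of its gene's counts, together with up to 3 members of each list with changed usage.

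Tests were first tested on simulated data with 100 genes seeded at 1.5-fold and 100 at 2-fold. In simulated MYB-experiment libraries 86 and 96 of these were recovered, with 8 false calls among 15592 genes. The gene test recovered 68 and 88 in simulated 34kn libraries with 12 false calls among 15836 genes, and 64 and 89 in simulated 34kp libraries with 6 among 16340. The bin test recovered 3 bins at 1.5-fold and 37 at 2-fold in simulated 34kn libraries, with 24 false calls among 210655 bins, and 0 and 28 in simulated 34kp libraries, with 16 among 214587. With a single dispersion per gene, a simulation added afterwards, 0 and 13 were recovered with 0 false calls among 211115 bins. The bin test therefore misses most usage changes of 1.5-fold and of 2-fold at this depth.

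Alternatives were RLE scaling, DESeq2's Wald test, no count filter, a minimum count of 50, an absolute log2 fold change of at least 1, a replicate block, leaving out each library in turn, other sets of libraries in the fit, limma voom with diffSplice, the DEXSeq-type model, an estimated correlation and fry. After seeing the data, removal of each library's GC trend (a loess of span 0.3 on gene GC content, for 97.2% to 97.6% of tested genes), a 5′ coverage index as a term for exon usage, and leaving out libraries in the list tests were added. The index of a library is the median log2 ratio of a gene's share of counts in its first 0.1 of bins to the geometric mean of that share over the 12 libraries, over 3627 genes with at least 10 bins and a mean count of at least 50 there, MYB left out. A check of bin GC content was void because too few bins could be given coordinates. The deposited files hold 46 MYB bins, numbered in transcript order, and no bin coordinates are given here because the annotation release that defined them was not given in the sources used here.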

Results

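RNA of 21 K562 libraries was measured by sequencing in 3 experiments. In the 34kn and 34kp experiments an eRNA from the enhancer upstream of MYB was overexpressed and set against 3 control libraries each, and exon bins were counted. In the third experiment, gene counts were given for 3 empty-vector libraries, 3 libraries labelled MYB overexpression and 3 labelled NMYB overexpression. Bin counts per library summed to between 36765581 and 40040021 in the 34kn controls and between 36563252 and 39784097 with 34kn overexpression. They summed to between 39479722 and 40205566 in the 34kp controls and between 37941434 and 41243796 with 34kp overexpression. Gene counts summed to between 17672678 and 20276276 for empty vector, 19425246 and 24462819 for MYB and 16552237 and 19919918 for NMYB. In a principal component analysis, the first component of the gene table held 39.3% of the variance and set the empty-vector libraries apart from the other 6. Over the 12 bin libraries the first component, with 39.8%, separated the experiments. Within the 34kp libraries it separated control from overexpression with 35.4%, and within the 34kn libraries it carried 35.3%, with all controls above all overexpression libraries and control 1 farthest from the rest.

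MYB encodes the transcription factor c-Myb, which keeps haematopoietic progenitors proliferating (GENCODE 29, GRCh38, chromosome 6, 135181315 to 135219173, plus strand, with 42 annotated transcripts). Its level was 215.2 ± 4.43 CPM in empty-vector libraries, 226.9 ± 4.53 CPM in libraries labelled MYB overexpression and 211.4 ± 8.38 CPM in libraries labelled NMYB overexpression (n = 3 each). The log2 fold change against empty vector was 0.08 (SE 0.0437, adjusted p = 0.230 by edgeR) for MYB, with a 95% interval of the fold from 0.990 to 1.12. For NMYB it was −0.03 (SE 0.0439, adjusted p = 0.727), with an interval from 0.922 to 1.047. Between NMYB and MYB it was −0.10 (SE 0.0437, adjusted p = 0.229), with an interval from 0.875 to 0.993. These intervals are not adjusted over genes. The MYB transcript was thus not detectably raised in the libraries whose label names its overexpression, and the direction of comparisons with them rests on the label. Reads from a construct without the counted exon sequence would not be in these counts, but those of an unaltered full-length coding sequence would. These values cannot tell an uncounted construct from a weak or absent overexpression or a wrong label. In the bin sums, scaled over 12 libraries, MYB stood at 184.7 ± 20.2 CPM in 34kn controls and 208.5 ± 3.09 CPM with 34kn overexpression, and at 202.3 ± 3.36 CPM in 34kp controls and 213.0 ± 18.6 CPM with 34kp overexpression (n = 3 each). The log2 fold change was 0.17 (SE 0.0761, adjusted p = 0.205) for 34kn and 0.07 (SE 0.0788, adjusted p = 0.699) for 34kp. Without 34kn control 1, the lowest of the controls, the 34kn value was 0.09 (adjusted p = 0.3505), and without control 2 it was 0.24 (adjusted p = 0.0313), so size and call depend on single controls. Without control 2 edgeR called 2982 genes in all, so that call is not particular to MYB.

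**Figure D1:**
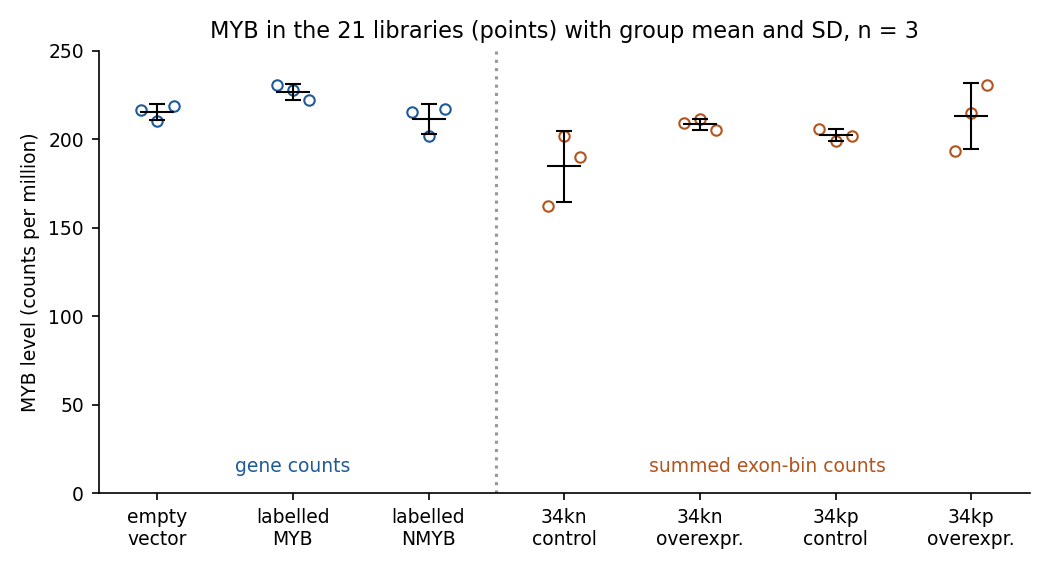
Level of MYB in CPM (vertical axis, from 0) in each of the 21 libraries (points) by group (horizontal axis), with the mean and SD of 3 libraries. Gene counts are on the left of the dotted line and summed exon bin counts on the right, with means from 184.7 CPM in 34kn controls to 226.9 CPM in libraries labelled MYB.

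The neighbours of MYB on chromosome 6 are HBS1L, which encodes a translation factor of ribosome rescue (134960378 to 135103056, minus strand, 78.3 kb upstream of the MYB start), and AHI1, a ciliary transition zone gene (135283532 to 135497776, minus strand). AHI1 fell in libraries labelled MYB by 0.37 and in libraries labelled NMYB by 0.50 on the log2 scale (adjusted p = 9.03e-05 and 5.06e-06). HBS1L stood at −0.04 (adjusted p = 0.542) and −0.12 (adjusted p = 0.0715). In the eRNA experiments neither neighbour passed the test, with HBS1L at 0.18 (adjusted p = 0.157) for 34kn, or adjusted p = 0.0301 without 34kn control 2, and at 0.00 (adjusted p = 0.983) for 34kp. AHI1 stood at 0.08 (adjusted p = 0.609) and 0.02 (adjusted p = 0.965). Without 34kn control 2 edgeR called 2982 genes in all, so the HBS1L call in that setting is not particular to this locus. MYB-AS1, antisense within MYB (135195083 to 135195995), stood between −0.43 and 0.33 in the 4 comparisons with a control, with adjusted p from 0.206 to 0.725, and shares reads with MYB if the counting ignored strand.

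The comparison of libraries labelled MYB overexpression with empty vector asks what full-length MYB changes in these cells. Cholesterol synthesis, glycolysis and hypoxia genes and replication-dependent histone genes fell together. INSIG1, which holds the sterol sensor of the endoplasmic reticulum in place (chromosome 7, 155297776 to 155310235), fell from 240.5 ± 5.48 to 103.3 ± 2.65 CPM (log2 fold change −1.22, SE 0.0459, adjusted p = 8.21e-13). The brain-type aldolase gene ALDOC fell from 158.8 ± 7.80 to 57.2 ± 3.21 CPM (−1.47, SE 0.0614, adjusted p = 4.10e-12). PLCD1, a phospholipase C gene (chromosome 3, 38007496 to 38029762), fell from 120.1 ± 2.2 to 36.0 ± 1.00 CPM (−1.74, adjusted p = 2.75e-13). SERPINB9, an inhibitor of granzyme B (chromosome 6, 2887266 to 2903280), fell from 91.5 ± 0.918 to 28.1 ± 0.549 CPM (−1.70, adjusted p = 2.34e-13). CALB1, a calcium-binding protein gene, rose from 34.7 ± 2.71 to 79.5 ± 2.48 CPM (1.19, SE 0.0654, adjusted p = 1.98e-10). THBS1, which encodes the matrix protein thrombospondin, rose from 2.66 ± 0.524 to 7.66 ± 0.573 CPM (1.54, adjusted p = 2.75e-07). The imprinted transcript H19 fell by 2.5 and the interleukin 9 receptor gene IL9R by 2.36 on the log2 scale.

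Of 21 cholesterol synthesis genes tested, 0 rose and 19 fell, and the same counts held adjusted over the list alone (median log2 fold change −0.55, camera adjusted p = 1.06e-37, and adjusted p = 1.85e-04 with an estimated correlation). Examples are the squalene synthase gene FDFT1 (−0.68) and the sterol carrier gene STARD4 (−1.07). Of 28 glycolysis and hypoxia genes 22 fell, 24 adjusted over the list alone, and none rose (median −0.36, adjusted p = 2.29e-31, and adjusted p = 0.00523 with an estimated correlation), among them the glucose transporter gene SLC2A3 (−0.85) and the angiogenic factor gene VEGFA (−0.74). Of 22 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 15 fell by either adjustment (median −0.40, adjusted p = 6.80e-11, and adjusted p = 0.00901 with an estimated correlation), among them H1-2 (−0.56) and H2BC21 (−0.67). The other 5 lists called by camera lost the call with an estimated correlation. Of 8 epithelial and kidney line markers 3 fell, 5 adjusted over the list alone (adjusted p = 7.83e-04, and adjusted p = 0.0559 with an estimated correlation), namely the keratin genes KRT8 (−0.77), KRT18 (−0.42) and KRT19 (−0.41), of which the first pair have many near-identical pseudogenes. Of 13 heat shock genes 6 rose, with 1 more falling adjusted over the list alone (adjusted p = 0.00591, and adjusted p = 0.0870 with an estimated correlation), among them HSPH1 (0.29) and HSPE1 (0.40). Of 16 immediate early genes 2 rose and 6 fell, 2 and 7 adjusted over the list alone (adjusted p = 0.00591, and adjusted p = 0.415 with an estimated correlation), with EGR1 at −0.66, FOS at −1.11 and NR4A1 at −0.82. Of 15 mitochondrially encoded genes 2 rose and 7 fell, 2 and 9 adjusted over the list alone (adjusted p = 0.0103, and adjusted p = 0.594 with an estimated correlation), a call that ended without empty vector 1 (adjusted p = 0.0613). Of 14 megakaryocytic genes 2 rose and 5 fell by either adjustment (adjusted p = 0.0139, and adjusted p = 0.209 with an estimated correlation), with the platelet collagen receptor gene GP6 at −0.99 and THBS1 among those that rose. With the GC trend of each library removed, the immediate early call ended (adjusted p = 0.205).

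Erythroid genes as a list were not called (37 tested, 5 rose and 14 fell, 5 and 16 adjusted over the list alone, adjusted p = 0.116), though the transferrin receptor gene TFRC fell (−0.31). Among 15 erythroid transcription factors 3 rose and 6 fell (adjusted p = 0.334), with LMO2 at −0.46, NFE2 at −0.34 and GATA1 at −0.29. Of 18 reported MYB target genes 4 rose and 4 fell by either adjustment (adjusted p = 0.911), among them BMI1, a Polycomb gene, at 0.34. Splicing factors (45 tested, 8 rose and 2 fell), chromatin looping and cofactor genes (18, 6 and 2) and mitosis genes (29, 0 and 7) had camera adjusted p of 0.116, 0.0593 and 0.0839, with LUC7L2 at 0.59, HNRNPU at 0.25 and the spindle checkpoint gene BUB1 at −0.36. Interferon response genes counted 5 risen and 1 fallen of 16 (adjusted p = 0.129), with the antiviral sensor gene OAS3 at 1.44 and IFITM1 at −0.49. Amino acid stress and unfolded protein response genes counted 5 risen and 1 fallen of 22 (adjusted p = 0.507), with the mTORC1 inhibitor gene DDIT4 at −0.72 and the chaperone gene CALR at 0.22. The remaining lists were not called. Fetal globin regulators counted 4 risen and 3 fallen of 19, granulocytic and monocytic genes 3 and 1 of 11, and stem and progenitor genes 1 and 2 of 9. DNA replication genes counted 2 and 4 of 29, cyclins and CDK inhibitors 1 and 2 of 15, and STAT5 and cytokine signalling genes 1 and 4 of 15. BCL2 family genes counted 1 and 1 of 11, NF-kB and inflammatory genes 1 and 1 of 11, small ribosomal protein genes 1 and 3 of 24, and fibroblast markers 1 and 2 of 6. Lists too short for the set test were the MYB family (0 of 3 changed), lymphoid markers (1 of 3, CD3D at −1.24) and MYB locus genes (1 of 4, AHI1).

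In all, edgeR called 3529 of 15823 genes in libraries labelled MYB, 1522 higher and 2007 lower, with a median absolute log2 fold change of 0.34, and 339 of them changed at least 2-fold. The groups did not overlap for 40.5% of genes, where chance gives 10%. Of the 87 calls behind named genes, 4 to 7 were lost on leaving out any 1 library. FTH1, an iron storage gene with many near-identical copies that rose by 1.88, was not called without empty vector 1, 2 or 3 or without MYB 2 or 3 (adjusted p = 0.114, 0.0783, 0.0989, 0.0947 and 0.105), and CCDC85B, at 2.08, was not called without MYB 3 (adjusted p = 0.0546).

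The comparison of libraries labelled NMYB overexpression with empty vector asks the same of the construct labelled NMYB. Cholesterol synthesis and glycolysis and hypoxia genes again fell. INSIG1 fell to 117.4 ± 3.57 CPM from 240.5 ± 5.48 (log2 fold change −1.03, SE 0.0458, adjusted p = 1.62e-11). SERPINB9 fell to 31.4 ± 1.49 from 91.5 ± 0.918 CPM (−1.54, SE 0.0558, adjusted p = 1.58e-12) and PLCD1 to 47.3 ± 4.03 from 120.1 ± 2.2 CPM (−1.35, SE 0.0588, adjusted p = 1.62e-11). HSPB1, which encodes a small heat shock protein, rose from 167.4 ± 20.4 to 361.5 ± 53.2 CPM (1.11, SE 0.117, adjusted p = 2.04e-04). The genes that rose most included FADD, an adaptor of death receptors (2.09, adjusted p = 7.01e-06), and ENDOG, a mitochondrial nuclease gene (2.28, adjusted p = 4.74e-04), both below 10 CPM. FTH1, uncertain because of its copies, stood at 396.6 ± 172 against 31.7 ± 8.68 CPM (3.65, adjusted p = 0.00282).

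Of 21 cholesterol synthesis genes 17 fell, 18 adjusted over the list alone (median −0.42, camera adjusted p = 6.37e-29, and adjusted p = 4.05e-04 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at −0.78. Of 28 glycolysis and hypoxia genes 1 rose and 19 fell, 2 and 20 adjusted over the list alone (adjusted p = 1.25e-15, and adjusted p = 0.0468 with an estimated correlation), with ALDOC at −1.07 and SLC2A3 at −0.82. Of 22 histone genes 13 fell, 16 adjusted over the list alone (adjusted p = 3.09e-06, and adjusted p = 0.0510 with an estimated correlation). Of 29 mitosis genes 1 rose and 11 fell, 2 and 11 adjusted over the list alone (adjusted p = 0.00373, and adjusted p = 0.330 with an estimated correlation), with the proliferation marker gene MKI67 at −0.32 and the topoisomerase gene TOP2A at −0.37. Of 24 small ribosomal protein genes, which have many processed copies, 10 rose, 11 adjusted over the list alone (adjusted p = 0.00373, and adjusted p = 0.289 with an estimated correlation), with RPS12 at 0.30. Mitochondrially encoded genes counted 1 risen and 8 fallen of 15, 1 and 10 adjusted over the list alone (adjusted p = 0.00126, and adjusted p = 0.521 with an estimated correlation). Heat shock genes counted 6 and 1 of 13 (adjusted p = 0.0235, and adjusted p = 0.157 with an estimated correlation) and interferon response genes 5 and 2 of 16, 7 and 2 adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.157 with an estimated correlation). The heat shock call ended without NMYB 1 (adjusted p = 0.0574) and the interferon call without NMYB 2 (adjusted p = 0.0637). With GC trends removed, the interferon, mitochondrial and mitosis calls ended (adjusted p = 0.146, 0.180 and 0.313). The other lists were not called, among them erythroid genes (6 rose and 7 fell of 37, adjusted p = 0.961), with the erythroid regulator gene KLF1 at 0.52, and reported MYB targets (3 and 4 of 18), with CEBPB, a myeloid transcription factor gene, at 0.99.

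For NMYB, edgeR called 3945 of 15823 genes, 1987 higher and 1958 lower, 367 of them at least 2-fold, and the groups did not overlap for 38.9% of genes. MYBL1, the MYB family member that rose (0.79, adjusted p = 0.0247), was not called without empty vector 1 or 2 or without NMYB 1 or 3 (adjusted p = 0.0820, 0.0828, 0.0618 and 0.0879).

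Both comparisons called 2335 genes, of which 2334 moved in the same direction, 1029 up and 1305 down, where independent lists would share 191 and 248. Fold changes correlated across genes with r = 0.820, which does not treat genes as independent replicates. Both comparisons use the same 3 empty-vector libraries, which alone gave a mean r of 0.517 in 10 simulations with no effect. The simulated groups had a mean of 1 and 0.2 calls, with 0 to 1 shared in the same direction. With so few calls, this count cannot show how much the shared controls add to the overlap of the real calls. The covariance of the fold changes was 0.117 against 0.0178 simulated, a difference of 0.0996. The 3 controls were also divided between the comparisons so that none was shared, a test chosen after the result was seen. Over 6 divisions the covariance was 0.0916 to 0.111 and r 0.508 to 0.612. Each division left a single empty-vector library to 1 of the comparisons. A shift common to all 3 empty-vector libraries would stay in both comparisons. Neither the simulations nor the divisions can tell it from an effect shared by the constructs.

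Libraries labelled NMYB were compared directly with those labelled MYB to ask how the effects of these constructs differ. EGR1, an immediate early transcription factor gene (chromosome 5, 138465490 to 138469315), was higher with NMYB, at 360.8 ± 11.8 against 292.6 ± 15.1 CPM (log2 fold change 0.30, SE 0.0436, adjusted p = 0.00888). ALDOC was higher at 75.8 ± 5.77 against 57.2 ± 3.21 CPM (0.40, SE 0.0627, adjusted p = 0.00888), and RNASET2, a lysosomal ribonuclease gene, by 0.53 (SE 0.0831, adjusted p = 0.00888). TEAD1, a Hippo pathway transcription factor gene, and MKI67 were lower with NMYB (−0.35, adjusted p = 0.0112, and −0.24, adjusted p = 0.0201). For EGR1 and ALDOC the NMYB level lay between that of MYB and that of empty vector, at 463.0 and 158.8 CPM. All the named calls of this comparison were lost without MYB 1, with EGR1, RNASET2 and TEAD1 each at adjusted p = 0.0824, ALDOC at 0.0688 and MKI67 at 0.163, and TEAD1 was lost without MYB 3 as well (adjusted p = 0.0532).

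In this comparison 181 of 15823 genes were called, 82 higher and 99 lower with NMYB, and none at least 2-fold. At an unadjusted p below 0.05 there were 2806, and DESeq2 called 435. Without MYB 1 edgeR called 0, without MYB 3 it called 24, without NMYB 1 it called 43 and without NMYB 3 it called 323, and the fold changes followed gene GC content with a Spearman correlation of 0.45 across genes. With GC trends removed 674 genes were called, 161 of them called in the same direction in both fits. Camera called 10 lists, none with an estimated correlation. Glycolysis and hypoxia genes (4 of 28 rose, 15 adjusted over the list alone) and small ribosomal protein genes (3 of 24, 15 adjusted over the list alone) were higher with NMYB (adjusted p = 2.54e-09 each, and adjusted p = 0.0783 each with an estimated correlation). Chromatin looping and cofactor genes were lower (2 of 18 fell, 9 adjusted over the list alone, adjusted p = 2.34e-05, and adjusted p = 0.0783 with an estimated correlation), with the Mediator gene MED1 at −0.24 and the cohesin loader gene NIPBL at −0.24. Erythroid genes were higher (1 of 37 rose, 11 with 1 fallen adjusted over the list alone, adjusted p = 0.00230, and adjusted p = 0.117 with an estimated correlation). Splicing factors were lower and epithelial markers, histones, cholesterol synthesis genes, erythroid transcription factors and immediate early genes higher. Their adjusted p was 0.00287, 0.00242, 0.00792, 0.01, 0.0211 and 0.0396, or 0.306, 0.0783, 0.151, 0.0917, 0.438 and 0.438 with an estimated correlation. Without MYB 2 the cholesterol, histone and erythroid transcription factor calls ended (adjusted p = 0.127, 0.0535 and 0.0881), and without NMYB 2 those of erythroid transcription factors and immediate early genes (0.185 each). The immediate early call also ended without MYB 1, MYB 3 or NMYB 3 (0.144, 0.0616 and 0.0660). With GC trends removed, glycolysis and hypoxia, small ribosomal protein and cholesterol genes were still called, and chromatin looping, epithelial, erythroid and histone genes were not (adjusted p = 0.152, 0.152, 0.159 and 0.139). Camera's direction then reversed without a call for immediate early genes, splicing factors and erythroid transcription factors (adjusted p = 0.122, 0.574 and 0.0948), while the medians of immediate early genes and splicing factors kept their sign (0.0067 and −0.0041).

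**Figure D2:**
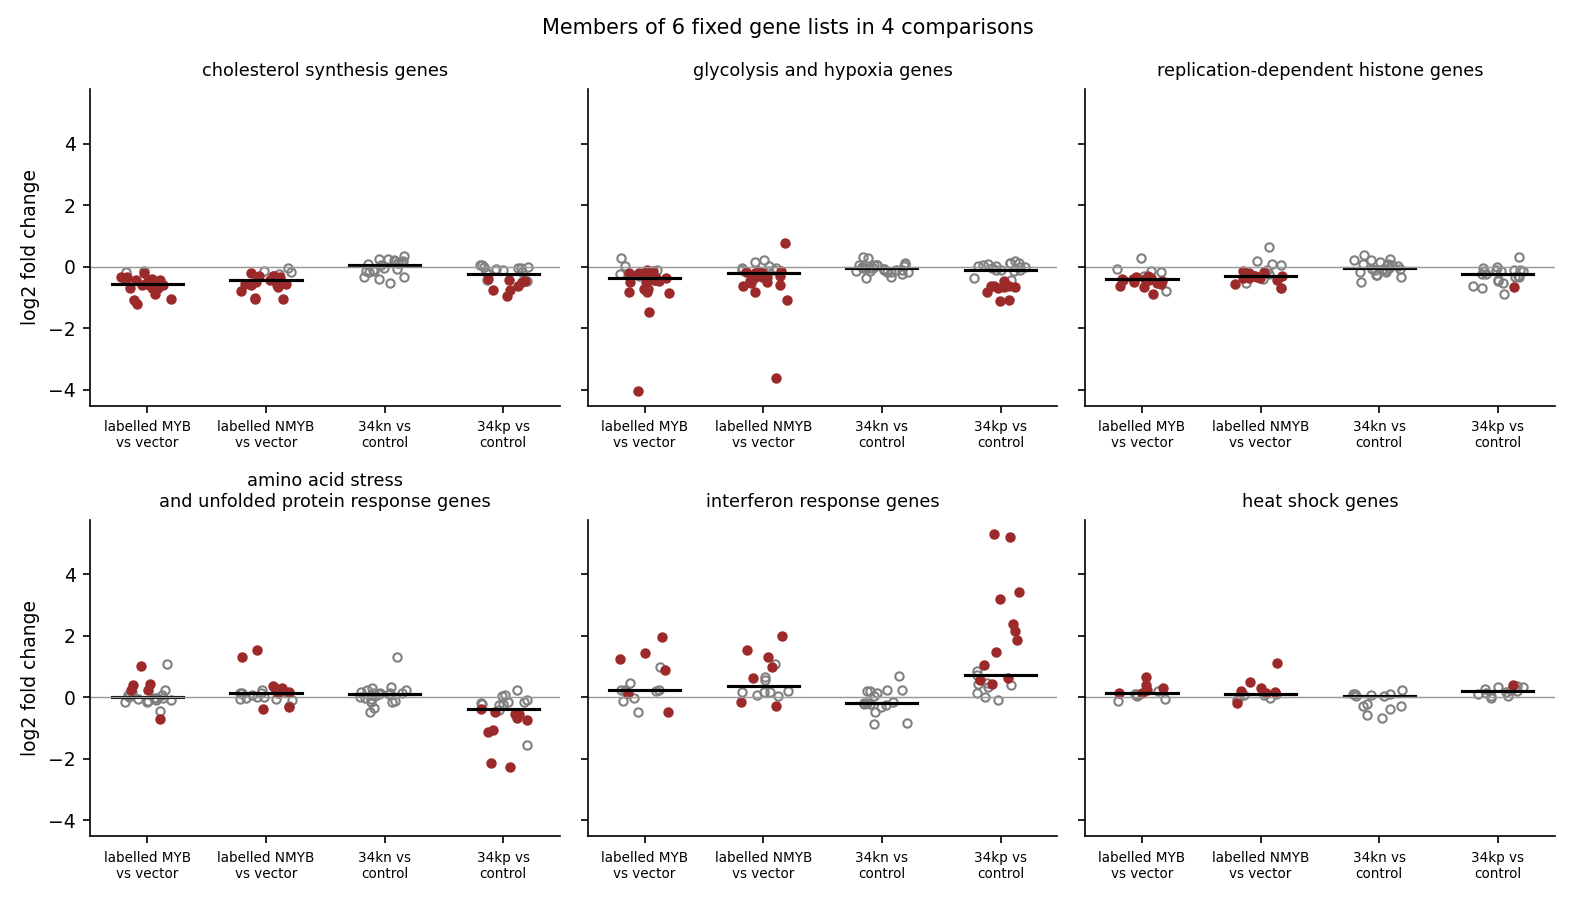
Log2 fold change (vertical axis) of each tested member of 6 gene lists in 4 comparisons (horizontal axis), with filled points for genes past an adjusted p of 0.05 and a bar at the list median. Cholesterol synthesis genes lie below 0 in libraries labelled MYB (median −0.55) and interferon response genes above 0 with 34kp overexpression (median 0.73).

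Overexpression of the 34kn eRNA was set against its controls to ask what this eRNA changes in gene levels and exon usage. At the gene level no gene passed the test in edgeR, with 0 of 16116 called and a smallest adjusted p of 0.0622. There were 3759 genes at an unadjusted p below 0.05, and DESeq2 called 1241. Without 34kn control 2 edgeR called 2982 genes and without 34kn control 1 it called 447. The groups did not overlap for 28.96% of genes, and the fold changes followed gene GC content with a Spearman correlation of −0.57 across genes. Camera called 4 lists, none with an estimated correlation (adjusted p = 0.640 for each). Mitochondrially encoded genes (8 of 12 risen adjusted over the list alone, median 0.22, adjusted p = 3.56e-04) and mitosis genes (11 risen and 2 fallen of 29, median 0.16, adjusted p = 0.00171) were higher. Immediate early genes (6 of 17 fallen, median −0.19, adjusted p = 0.00208) and erythroid transcription factors (1 risen and 7 fallen of 15, median −0.14, adjusted p = 0.0102) were lower. With GC trends removed, the mitochondrial call ended (adjusted p = 0.777), and camera's direction relative to the other genes reversed for mitosis genes, immediate early genes and erythroid transcription factors (adjusted p = 0.313, 0.0724 and 0.0227). The medians of mitosis and immediate early genes kept their sign (0.05 and −0.03). Without 34kn control 1, 7 lists were called. Erythroid genes (3 risen and 3 fallen of 36 adjusted over the list alone, adjusted p = 0.452), reported MYB targets (2 and 3 of 20, adjusted p = 0.858) and interferon response genes (adjusted p = 0.576) were not called.

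For exon usage edgeR called 1717 of 216197 tested bins with 34kn overexpression, 48 higher and 1669 lower, in 826 of 11407 genes, while the DEXSeq-type model called 26 bins in 12 genes. Bins near the 5′ end lost counts relative to the rest of their genes, as in ATP2A2, a calcium pump gene, where bin 003 fell from 0.607% to 0.0322% of the gene's counts (log2 usage −4.14, adjusted p = 2.25e-13 by edgeR), and AGAP3, where bin 004 fell from 0.959% to 0.0928% (−3.41, adjusted p = 5.03e-14). Bin 006 of CCNG1, a cyclin gene induced by p53, fell from 2.30% to 0.387% (−2.52, adjusted p = 2.54e-05). Bin 001 of MED10, a Mediator gene, rose from 4.38% to 8.42% (0.95, adjusted p = 0.00632), and was not called without 34kn control 3 or 34kn overexpression 1 or 2 (adjusted p = 0.139, 0.115 and 0.154). MED10 lies on the minus strand, so this bin was placed at the 3′ end of the gene. Genes with changed usage included 14 of 45 splicing factors, the longest list (3 bins up and 41 down, such as bins of HNRNPM and SRSF1), 8 of 29 DNA replication genes (0 up and 16 down, such as MCM2), 6 of 24 small ribosomal protein genes and 6 of 34 erythroid genes (3 up and 8 down, such as TAL1). No test of lists was made for exon usage.

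The lowered bins lay towards the 5′ end: of the lowered bins with a known position, which were 98.08% of the 1669, 65.2% were in the fifth of their gene nearest its start, against 15.96% of tested bins. The 5′ coverage index was 0.52, 0.06 and 0.18 in 34kn controls 1, 2 and 3 and −0.03, −0.04 and 0.01 with overexpression. With this index as a term 45 bins in 20 genes were called, 35 higher and 10 lower, and none of the 16 named bins. Without 34kn control 2 there were 8391 bins, without control 1 352 and without control 3 1129, and without overexpression 1, 2 and 3 there were 360.0, 253 and 715.

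For MYB itself the question is whether the eRNA shifts which promoter is used, which changes the share of its first bins. Of 46 bins 33 were tested, and 0 changed over all bins in edgeR, with 5 at an unadjusted p below 0.05 and a smallest adjusted p of 0.141. Adjusted over the MYB bins alone, 2 changed: bin 003 fell from 1.35% to 0.824% of MYB counts (log2 usage −0.70, SE 0.215) and bin 004 from 2.76% to 1.83% (−0.57, SE 0.173), with adjusted p = 0.0411 each. Bins 005, 006 and 007 stood at −0.48, −0.39 and −0.35. Without 34kn control 1 or 3, or overexpression 1, 2 or 3, 0 MYB bins were called in this way, and without control 2 there were 3. With the index as a term, the DEXSeq-type model, no filter or 12 libraries in the fit there were 0. With limma voom, a minimum count of 50 or a replicate block there were 3. Bins 001 to 007 together held 18.2%, 13.4% and 13.4% of MYB counts in the controls and 10.3%, 11.5% and 10.4% with overexpression.

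**Figure D3:**
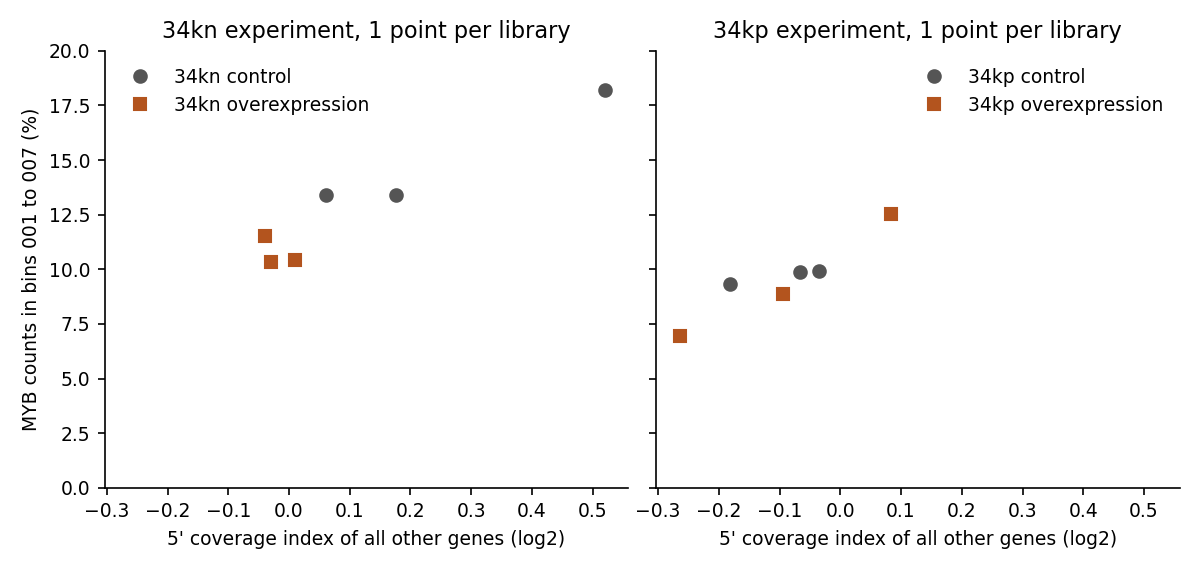
Share of MYB counts in bins 001 to 007 in percent (vertical axis) against the log2 5′ coverage index of other genes (horizontal axis), 1 point per library, for the 34kn and the 34kp experiment. The library with the highest index, 34kn control 1 at 0.52, also has the highest share, 18.2%.

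Overexpression of the 34kp eRNA was set against its own controls to ask the same. As lists by camera, interferon response genes were higher, and amino acid stress, cholesterol synthesis and glycolysis and hypoxia genes lower, with 12 of 21, 10 of 22, 8 of 21 and 10 of 27 members called. With an estimated correlation the cholesterol and glycolysis calls were lost (adjusted p = 0.0611 and 0.127). IFI27, an interferon-induced mitochondrial protein gene (chromosome 14, 94104836 to 94116698), rose from 1.72 ± 0.505 to 15.8 ± 2.11 CPM (log2 fold change 3.20, SE 0.1998, adjusted p = 2.41e-05). OAS3, an antiviral oligoadenylate synthetase gene (chromosome 12, 112938352 to 112973249), rose from 5.05 ± 1.13 to 18.3 ± 1.56 CPM (1.86, SE 0.163, adjusted p = 3.07e-04). ISG15, which encodes a ubiquitin-like modifier (chromosome 1, 1001138 to 1014540), rose from 8.59 ± 0.864 to 23.8 ± 5.03 CPM (1.47, SE 0.158, adjusted p = 0.00103). DDIT4 (chromosome 10, 72273920 to 72276036) fell from 386.3 ± 34.7 to 86.9 ± 20.1 CPM (−2.15, SE 0.143, adjusted p = 3.60e-05). CHAC1, a glutathione-degrading enzyme gene induced by amino acid stress (chromosome 15, 40952962 to 40956519), fell from 15.1 ± 1.54 to 3.11 ± 1.18 CPM (−2.28, SE 0.225, adjusted p = 5.91e-04).

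Of 21 interferon response genes 12 rose and 0 fell, 16 and 0 adjusted over the list alone (median 0.73, camera adjusted p = 1.19e-52, and adjusted p = 0.00189 with an estimated correlation). The unit of IFI6 and LINC02574, which the bin counts join, rose by 2.39 and PARP9, a gene of the interferon-induced DTX3L complex outside the list, by 1.13. Of 22 amino acid stress and unfolded protein response genes 10 fell, 13 with 1 risen adjusted over the list alone (median −0.40, adjusted p = 4.58e-24, and adjusted p = 0.00452 with an estimated correlation), among them HERPUD1 (−1.05), a gene of endoplasmic reticulum degradation, and the unit of DDIT3 (−1.12), the transcription factor CHOP. ATF3, a transcription factor gene of the same response listed here with immediate early genes, fell by 1.37. Of 21 cholesterol synthesis genes 8 fell, 11 adjusted over the list alone (adjusted p = 9.11e-11, and adjusted p = 0.0611 with an estimated correlation), with MSMO1 at −0.96 and INSIG1 at −0.75. Of 27 glycolysis and hypoxia genes 10 fell, 12 adjusted over the list alone (adjusted p = 9.11e-11, and adjusted p = 0.127 with an estimated correlation), with P4HA1, a collagen prolyl hydroxylase gene, at −1.11 and VEGFA at −0.64. Of 35 erythroid genes 6 fell, 11 with 1 risen adjusted over the list alone (adjusted p = 2.69e-04, and adjusted p = 0.0886 with an estimated correlation), with ALAS2, the erythroid enzyme of haem synthesis, at −0.61, a call that ended without 34kp control 2 (adjusted p = 0.0511). After removal of GC trends 10 lists were called, but 0 with an estimated correlation, where interferon response genes stood at adjusted p = 0.0650 and amino acid stress genes at 0.0861. Histone genes counted 1 fallen of 21, 1 risen and 8 fallen adjusted over the list alone (adjusted p = 2.46e-04, and adjusted p = 0.135 with an estimated correlation).

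Lists that were higher included heat shock genes (1 of 13 rose, 6 adjusted over the list alone) and splicing factors (4 rose and 1 fell of 45, 10 and 2 adjusted over the list alone). Others were mitochondrially encoded genes (2 of 12, 3 adjusted over the list alone), STAT5 and cytokine signalling genes (2 of 14, 4 adjusted over the list alone), fetal globin regulators (0 of 19) and stem and progenitor genes (0 of 9, 3 risen and 1 fallen adjusted over the list alone). Their adjusted p was 7.98e-05, 7.98e-05, 4.94e-04, 0.00213, 0.0403 and 0.0403, or 0.127, 0.127, 0.486, 0.229, 0.343 and 0.247 with an estimated correlation. The fetal globin call ended without 34kp control 1 or 2 or overexpression 1 or 2 (adjusted p = 0.104, 0.0567, 0.0699 and 0.0809), the stem and progenitor call without control 1 or 3 or overexpression 1 (0.0777, 0.0733 and 0.0679) and the mitochondrial call without overexpression 3 (0.0589). With GC trends removed, the fetal globin and stem and progenitor calls ended (0.0508 and 0.0968). Reported MYB targets (2 rose of 21, adjusted p = 0.0690) and erythroid transcription factors (1 rose of 15, adjusted p = 0.0690) were not called.

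For 34kp, edgeR called 392 of 16662 genes, 105 higher and 287 lower, 98 of them at least 2-fold, and the groups did not overlap for 23.5% of genes. Among the counted items, reads of low alignment quality made up 4.55% ± 0.0920 with 34kp overexpression and 7.68% ± 0.612 in its controls (n = 3). The groups did not overlap in this measure, so a library or sequencing difference cannot be told apart from an effect of the eRNA on the called genes. Without 34kp control 1, 2 and 3 there were 139, 46 and 158, and without overexpression 1, 2 and 3 there were 614, 58 and 1175. Of 47 calls behind named genes 26 were lost without control 2 and 22 without overexpression 2, while IFI27, OAS3, ISG15, the IFI6 unit, DDIT4, CHAC1, HERPUD1, ATF3, MSMO1, INSIG1, P4HA1 and VEGFA were called without any 1 library. DESeq2 called 879 genes, 393 of them higher, and with GC trends removed 1872 were called, 890 of them higher. Of the 1872, 388 were called in the same direction in both fits. With all 12 libraries in the fit 342 of 817 were higher, with RLE scaling 113 of 373 and with a replicate block 14 of 71. The excess of lower genes thus depended on the fit.

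The test called 19 of 220442 bins with 34kp overexpression, 2 higher and 17 lower, in 10 genes, with 4822 at an unadjusted p below 0.05. Simulated 34kp libraries in which each bin had its own dispersion gave 16 false bin calls, so a count of 19 is near what the test can call falsely, and the bins named here are not established changes. Bin 001 of the DDIT3 unit rose from 3.78% to 8.005% of the unit's counts (log2 usage 1.08, adjusted p = 0.0381 by edgeR), while the unit as a whole fell. The unit lies on the minus strand, so this bin was placed at its 3′ end. Bin 042 of the unit of CYTOR, a long noncoding RNA gene with near-identical copies, fell from 4.18% to 1.67% (−1.32, adjusted p = 9.22e-05), and bin 093 of MARS1, which encodes methionyl-tRNA synthetase, fell by 1.12 (adjusted p = 1.61e-04). The DDIT3 call ended on leaving out any library except 34kp overexpression 1, with adjusted p from 0.0773 without overexpression 3 to 1.00 without control 2, and those of CYTOR and MARS1 ended without control 2 (adjusted p = 0.0666 each). Without control 2, control 3 and overexpression 2 there were 4, 11 and 8 bins, without overexpression 3 there were 60.0, and with the index as a term 193. Of 34 tested MYB bins 0 changed over all bins or over the MYB bins alone, with 0 at an unadjusted p below 0.05 and a smallest adjusted p of 0.967 over the MYB bins. Bins 001 to 007 held 9.31%, 9.87% and 9.91% of MYB counts in the controls and 12.6%, 8.88% and 6.95% with overexpression.

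The difference between the effects of the eRNAs was tested as an interaction, given as the 34kn effect minus the 34kp effect. Amino acid stress genes had the lowest camera p of the lists, with 13 of 22 higher and 1 lower, 15 and 1 adjusted over the list alone (median 0.60, camera adjusted p = 1.73e-19, and adjusted p = 1.79e-04 with an estimated correlation), and interferon response genes were lower in 10 of 21, 11 adjusted over the list alone (median −0.71, adjusted p = 5.30e-14, and adjusted p = 0.00376 with an estimated correlation). Cholesterol synthesis genes were higher in 9 of 21, 10 adjusted over the list alone (adjusted p = 1.76e-06, and adjusted p = 0.0125 with an estimated correlation), and heat shock genes lower in 6 of 13 (adjusted p = 4.38e-04, and adjusted p = 0.0451 with an estimated correlation). IFI27 differed by −3.07 and DDIT4 by 1.82 on the log2 scale (adjusted p = 2.33e-04 for IFI27). Both were picked for large 34kp changes, and their 34kn fold changes were 0.14 and −0.34. In all 1102 of 17323 genes differed, 491 higher and 611 lower, and 731 of 235683 bins in 360.0 genes. The differences followed gene GC content with a Spearman correlation of −0.39 across genes. With GC trends removed 1418 genes were called, of which 817 were called in the same direction in both fits. Of 36 tested MYB bins 0 differed over all bins or over the MYB bins alone, with 0 at an unadjusted p below 0.05. Each experiment has its own controls, and whether the experiments were done together is not given in the sources used here. Without 34kn control 1, 2 and 3 the gene count was 603, 1867 and 603, without 34kn overexpression 1, 2 and 3 it was 404, 449 and 528, without 34kp control 1 and 2 it was 417 and 380.0, and without 34kp overexpression 1, 2 and 3 it was 638, 482 and 2747. The bin count was 65.0, 2441, 347 and 257 without 34kn control 1, 34kn control 2, 34kn overexpression 1 and 34kn overexpression 2, and 220.0, 397, 73.0, 437 and 2871 without 34kp control 1, 34kp control 2, and 34kp overexpression 1, 2 and 3.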

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

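Tests of the coverage of 5′ bins within the 34kp overexpression libraries and of the position of lowered bins were chosen after the result was seen, as were the 5′ coverage index as a term and the splits made within each experiment.

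The 34kn and 34kp effects differed by the interaction test in 1102 genes and in 731 bins of 360.0 genes, given as 34kn minus 34kp. By camera adjusted p, the lists that differed were amino acid stress and unfolded protein response genes (1.73e-19), interferon response genes (5.30e-14), cholesterol synthesis genes (1.76e-06), glycolysis and hypoxia genes (2.94e-04) and heat shock genes (4.38e-04). Further lists were erythroid transcription factors (0.00506), mitosis genes (0.00509), immediate early genes (0.00648), splicing factors (0.00648), STAT5 and cytokine signalling genes (0.00736), replication-dependent histone genes (0.0143) and fetal globin regulators (0.0228). With an estimated correlation amino acid stress, interferon, cholesterol and heat shock genes held, at adjusted p = 1.79e-04, 0.00376, 0.0125 and 0.0451, and glycolysis and hypoxia genes stood at 0.185. All the further lists lost the call with an estimated correlation. After removal of GC trends mitosis genes (adjusted p = 0.983), STAT5 genes (0.969) and fetal globin regulators (0.523) were no longer called, and camera's direction reversed for immediate early genes (0.820) and erythroid transcription factors (0.512), whose medians stayed below 0 (−0.10 and −0.03). With an estimated correlation as well, 6 lists were called, heat shock genes were not (0.0967), and glycolysis and hypoxia genes (0.0147), erythroid genes (0.0147) and histone genes (0.0151) were. The fetal globin call ended without 34kp overexpression 2 (adjusted p = 0.05004) and the histone call without 34kp overexpression 3 (0.0613).

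Genes named for 34kp that differed were lower in the 34kn effect for IFI27 (−3.07), OAS3 (−2.07), ISG15 (−1.79), EGR1 (−1.56), HELZ2 (−1.25), IRF7 (−1.23), MT-TQ (−1.18) and PARP9 (−1.03). They were higher for CHAC1 (2.23), ASNSP1 (2.17), DDIT4 (1.82), INHBE (1.63), ATF3 (1.57), INSIG1-DT (1.57), MIR210HG (1.49) and LRP1 (1.34). The interaction's adjusted p ran from 2.69e-05 for ATF3 to 0.0252 for LRP1. These genes were picked for large 34kp changes in the same libraries, so the picking favours differences of this sign and size. Their 34kn fold changes ran from −0.45 for MIR210HG to 0.54 for ASNSP1, with IFI27 at 0.14 and CHAC1 at −0.05. The differences are therefore not a separate response to 34kn. ASNSP1 is a pseudogene of ASNS, so its reads cannot be told apart from those of ASNS.

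Of 100 drawn splits of the 12 libraries 2 gave as many as 1102 interaction genes, the real one included. These splits mix the experiments, which differ by themselves, so their share cannot decide on chance for the count. The highest other split called 1775, kept the 3 34kp controls together, and points to the difference between the experiments as a structure of the samples. Among 100 splits within each experiment 1 gave as many, the real one, with 509 as the highest other, a share under 0.05. Chance within the experiments is thus unlikely for the count, though it ran from 380 to 2747 on leaving out single libraries. For bins, 2 of 25 splits gave as many as 731 bins and 360.0 genes, with 2019 and 804 as the highest other, so chance could not be excluded. Those splits mix the experiments, and among 100 splits within each experiment 7 gave as many bins and 7 as many genes, the real one included, with 4069 and 1569 as the highest other, so chance could not be excluded there either. Splits that call several times the real count point to a structure of the samples within the experiments as well.

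The share of reads deposited as ambiguous, which no comparison used, was 0.0221% ± 0.000506 with 34kp overexpression and 0.0163% ± 0.000717 in its controls (n = 3), against 0.0158% and 0.0164% in the 34kn groups. Reads of low alignment quality made up 4.46% to 4.64% with 34kp overexpression and 7.15% to 8.35% in its controls. Neither measure overlapped between these groups. The 34kp changes in genes and lists, and the interaction, thus cannot be told apart from a library or sequencing difference between them.

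Of the 1669 bins lowered with 34kn overexpression, 65.2% of those with a known position lay in the fifth of the gene nearest its start, against 15.96% of tested bins. Their median log2 share ranged by 1.14 within the 34kp overexpression libraries (−6.80 to −5.66), against a 34kn group difference of 1.02, and from −6.15 to −4.99 in 34kn controls, but less in 34kp controls (−6.64 to −6.12) and with 34kn overexpression (−6.73 to −6.53). With the 5′ coverage index as a term, 10 bins were lowered, but the index itself followed the 34kn groups with r = 0.699, so this term could also remove an effect of the eRNA. The coverage of the first part of genes between libraries, as RNA integrity or library preparation can change it, is a candidate explanation for most of these calls. An effect of the 34kn eRNA on promoter use stays open and cannot be told apart from it for genes in which both would lower the same bins.

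The same applies to MYB bins 003 to 007. In the 34kp experiment, whose groups did not differ in these bins, the share of MYB counts in bins 001 to 007 followed the index of all other genes over 6 libraries, with rho = 0.943 (exact p = 0.0167, adjusted 0.0241 over 4 tests) and r = 0.940 (exact p = 0.0181, adjusted 0.0241). Without the 2 libraries farthest from the median index, overexpression 1 and 3, r was 0.562 over 4 libraries, so the relation rests in part on them. In the 34kn experiment r was 0.957 (exact p = 0.0139, adjusted 0.0241) and rho 0.771 (exact p = 0.103, adjusted 0.103), and r was 0.714 without controls 1 and 3. There the index itself followed the groups (r = 0.699), and the exact test exchanged libraries across groups. A group difference in both values could give this relation, so it cannot tell uneven coverage from an effect of the eRNA. Given the relation in the 34kp libraries, uneven coverage of the first part of genes may account for the lower share of these MYB bins. A shift between MYB promoters is not excluded.

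Comparisons of 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split called 3529 genes for MYB (1 of 10 splits as large, highest other 1), 3945 for NMYB (1 of 10, highest other 0) and 181 between NMYB and MYB (1 of 10, highest other 0). It called 392 genes for 34kp (1 of 10, highest other 0), and for 34kn genes all 10 splits gave 0. For 34kn bins the real split called 1717 bins in 826 genes (1 of 10), and the highest other 744 in 318. For 34kp bins 3 of 10 splits gave as many as 19 bins in 10 genes, the highest other called 203 in 84, joined controls 1 and 2 with overexpression 3, and points to a structure of the samples.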

How the results depend on the processing

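The values with GC trends or with the 5′ coverage index, and the list tests without single libraries, were chosen after the data were seen. Across alternatives, 305 of 425 values that answer a comparison held their direction and side of the threshold, or stayed within 1.5 times for a count, as did 513 of 612 for called lists, 3191 of 3509 for named genes and 227 of 319 for named bins. Of called lists 91 lost the call and in 8 camera's direction reversed, and 315 named-gene and 92 named-bin values lost it. Unless an alternative's construction is given, the cause was not tested.

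An absolute log2 fold change of at least 1, which removes smaller changes by construction, left 339 genes for MYB, 367 for NMYB, 0 between NMYB and MYB, 98 for 34kp and 198 for the interaction. It left 204 shared genes, and 968 bins in 531 genes for 34kn. With no filter there were 656 genes between NMYB and MYB, 1572 for 34kn, 997 for 34kp and 2085 for the interaction. DESeq2 called 435, 1241, 879 and 2011 in the same order. RLE scaling gave 195 genes between NMYB and MYB, 68 of them higher, against 82 of 181. With only the 6 libraries of both groups 60.0 genes differed between NMYB and MYB, and with all 12 libraries in the fit 817 were called for 34kp. Removal of GC trends gave 674 genes between NMYB and MYB, 6 for 34kn, 1872 for 34kp and 3646 in the overlap, with 437 of the 674 and 890.0 of the 1872 higher, against 82 of 181 and 105 of 392.

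For exon usage, the index as a term gave 45 bins in 20 genes for 34kn, 193 in 92 for 34kp and 58 in 26 for the interaction. Higher bins were then 35 of 45 for 34kn, against 48 of 1717, and 49 of 58 for the interaction, against 37 of 731. The DEXSeq-type model gave 26 bins in 12 genes for 34kn, and limma voom 318 in 198 for the interaction. Over the MYB bins alone 0 were called for 34kn with no filter, with the index, with 12 libraries or with the DEXSeq-type model, against 2. There were 2 with RLE scaling, and 3 with limma voom, with a minimum count of 50 or with a replicate block.

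With an estimated correlation 3 lists were called for MYB, 2 for NMYB, 0 between NMYB and MYB, 0 for 34kn, 2 for 34kp and 4 for the interaction. Removing GC trends gave 6 lists between NMYB and MYB, of which glycolysis, small ribosomal protein and cholesterol genes were among the original calls and mitochondrially encoded (adjusted p = 0.0130), fetal globin (0.0266) and mitosis genes (0.0485) were new. For 34kn it gave 8, or 0 with an estimated correlation, and no original call was kept in its direction. New calls there were higher amino acid stress (0.00138), STAT5 (0.0127), NF-kB (0.0223), granulocytic and monocytic (0.0227) and stem and progenitor genes (0.0395). Splicing factors (0.00138) and heat shock genes (0.0127) were newly called as lower. Lists whose camera direction, which is relative to the other genes, then reversed were, between NMYB and MYB, immediate early genes (adjusted p = 0.122), splicing factors (0.574) and erythroid transcription factors (0.0948), for 34kn mitosis genes (0.313), immediate early genes (0.0724) and erythroid transcription factors (0.0227), and for the interaction immediate early genes (0.820) and erythroid transcription factors (0.512).

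Libraries with the same replicate number did not deviate together in the fits of each eRNA experiment (correlations of −0.185 to 0.00799), so the numbers show no pairing there. In the MYB experiment these correlations were −0.0232 to 0.0994, against −0.122 to 0.0858 for libraries with other numbers. A weak pairing in that experiment is therefore not excluded. A replicate block gave 1184 genes between NMYB and MYB, 71 for 34kp and 651 for the interaction, 8 bins in 4 genes for 34kp and 310.0 in 174 for the interaction. Other counts stayed within 1.5 times, such as 4342 genes for MYB, 4713 for NMYB and 1244 bins for 34kn.

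Leaving out each library gave 2491 to 2889 genes for MYB, 2711 to 3900 for NMYB, 0 to 323 between them, 0 to 2982 for 34kn, 46 to 1175 for 34kp and 380.0 to 2747 for the interaction. It gave 253 to 8391 bins in 111 to 2646 genes for 34kn, 4 to 60.0 in 3 to 34 for 34kp and 65 to 2871 in 34 to 1259 for the interaction. Over MYB bins alone 0 to 3 were called for 34kn, and 0 to 3 over all bins. The log2 fold change of MYB for 34kn was 0.0886 without control 1 (adjusted p = 0.3505) and 0.2386 without control 2, where it was called (adjusted p = 0.0313). Lists called for 34kn ranged from 4 to 7, and shared genes from 1636 to 2465.

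In the seeded counts, 86 of 100 genes changed 1.5-fold were recovered for MYB and 3 of 100 bins for 34kn. Of 100 bins changed 2-fold, 37 were recovered for 34kn and 28 for 34kp. Absent bin calls thus say little about changes of either size.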

Other observations

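Tests of the share of counts in the highest genes and of a shared culture state were chosen after the result was seen, as was the removal of GC trends. The limit used to judge the culture-state correlation was set with that correlation already seen.

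Single genes outside those led with above also changed in both libraries labelled MYB and those labelled NMYB, while the lists of cyclins and CDK inhibitors (adjusted p = 0.507 and 0.356), STAT5 and cytokine signalling genes (0.455 and 0.710) and BCL2 family genes (0.908 and 0.961) were not called. UNG, which removes uracil from DNA, rose by 0.42 in both (adjusted p = 1.67e-05 and 2.11e-05), and CDKN2C, an inhibitor of CDK4 and CDK6, by 0.48 and 0.57 (adjusted p = 2.47e-04 and 5.00e-05). SPRY4, a feedback inhibitor of growth factor signalling, fell by 0.53 and 0.54, and the survival gene MCL1 by 0.39 and 0.32. LYZ, which encodes lysozyme of myeloid cells, rose by 0.46 and 0.55, and CD3D, a T cell receptor gene, fell from 31.3 ± 0.498 CPM to 13.3 ± 1.26 and 15.6 ± 1.04 CPM (n = 3).

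With 34kp overexpression, CDKN1C, a CDK inhibitor gene, fell from 63.5 ± 4.26 to 37.3 ± 1.64 CPM (log2 fold change −0.77, adjusted p = 0.00211). MIR210HG, host of a hypoxia-induced microRNA, fell by 1.95 (adjusted p = 3.19e-04), and INHBE, an activin subunit gene induced by amino acid stress, by 1.59 (adjusted p = 0.00234). The cyclin gene CCND1 rose by 0.73, and was not called without 34kp control 2 (adjusted p = 0.0903) or overexpression 2 (0.0754). The splicing factor gene SRSF3 rose by 0.46, and was not called without the same libraries (0.1055 and 0.0610).

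Cholesterol synthesis genes were lower in libraries labelled MYB although MYB itself was not detectably raised. After removal of GC trends the list's median was −0.50 against −0.55, and the list was still called, which argues against GC content as the whole cause. The log2 ratio of counts outside the 10 highest genes was 0.0120, far below the list's change. A few genes taking the counts would move all other genes alike, and TMM scaling adjusts for that. This value therefore says little about a fall relative to other genes. The list was also lower in the 34kp experiment, which has its own controls, with 8 of 21 genes called, though not with an estimated correlation (adjusted p = 0.0611, or 0.0960 with GC trends removed), and the MYB and 34kp fold changes correlated weakly across 12522 genes (r = 0.0941, rho = 0.123), with 106 of 141 shared calls in the same direction. With 34kn overexpression the list was not lower (median 0.07, adjusted p = 0.807), so a state common to all overexpression cultures was not seen, and one limited to some of them, such as density or medium use, stays open, since such measures are not given in the sources used here.

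The difference between libraries labelled NMYB and MYB followed GC content across genes with a Spearman correlation of 0.45. Once GC trends were removed 674 genes were called against 181, of which 161 were called in both in the same direction. The count also rose in the other comparisons on this removal, as from 392 to 1872 for 34kp, so the rise itself decides nothing. The 161 calls kept of 181 argue against GC bias as the whole cause of those calls. Without MYB 1 no gene was called, yet EGR1 stood at 0.28 and ALDOC at 0.45 against 0.30 and 0.40, so for these genes the lost calls do not show that a single library made the difference. A difference between the constructs stays open.

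Fold changes of the 34kn effect correlated across genes at −0.0237 with those of MYB, −0.162 with NMYB and −0.157 with 34kp. The 34kp effect correlated at 0.0657 with that of NMYB. Genes are not independent replicates in these values.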
